A study of Rattus norvegicus with 12 samples.

How the data were processed

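RNA of rat organotypic co-cultures of entorhinal cortex and hippocampus was measured on 12 arrays of 2 colours, each holding axotomized RNA in one dye and non-axotomized RNA in the other. Per the labels, the arrays are whole-genome rat oligonucleotide arrays of Agilent, the species is Rattus norvegicus, and the cultures were axotomized after 15 days in vitro; the treatment protocol in the same labels speaks of mice, a conflict that the sources used here do not settle. Per the labels, each of the 3 days (1, 3 and 7 after axotomy) has 2 biological replicates and each replicate has 2 arrays with exchanged dyes, so 6 biological replicates were analysed. Whether a replicate is 1 culture, 1 animal or a pool is not given in the sources used here, nor are scan dates or array batches.

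The deposited table holds log2 ratios of the 2 channels for 44290 spots, with no missing value. Per the submitters' processing notes, the authors used limma, with no version given; background correction, normalization and log base are not stated. Base 2 was taken from the convention of limma, and base 10 is excluded by the range of the values, so a reading in another base would rescale every ratio by 1 factor. The median of a column lay between -0.022 and 0.027, and the median absolute deviation between 0.140 and 0.145, so the columns had been centred near 0; whether the authors also scaled the arrays to each other stays unknown.

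The direction of the ratios was read from the values and the labels. On 733 spots the part of the ratio that turns with the dyes was over 1 on the log2 scale. Of these, 731 have no listed gene. The median of these 731 was -4.58 with the axotomized RNA in Cy5 and 3.92 with it in Cy3. Over the genes, the part that turns with the dyes was shared between replicates of different days (r of 0.39 to 0.65), as an effect of the dyes would be, while for the part that keeps its sign r ran from -0.29 to 0.35, above 0 for all pairs of days 1 and 3. Every column therefore likely runs in 1 RNA direction. That this direction is axotomized over non-axotomized is likely from the array titles and the order of the channels, and is not stated; if it is the other way, every sign turns.

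Spots were assigned to genes by the symbols that come with the table: 23535 spots have 1 symbol, 48 have several and 20707 have none. The mean of all spots with exactly 1 symbol gave 14871 genes, of which 5658 have 2 or more spots. Spots without a listed gene were kept in the test of single spots; control spots among them are not named in the table and were not removed. No value was scaled further. The table holds no signal intensity, so dim spots were not filtered.

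The 2 arrays of a biological replicate were averaged. The 6 resulting values per gene were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per day tested against 0 (two-sided, Benjamini-Hochberg over all genes of that day, adjusted p under 0.05). The 3 days share 1 estimate of the spread, with 3 residual and 2.72 prior degrees of freedom. The same fit gave the average of the 3 days, the 3 differences between days and an F test over the days, and a second fit treated each spot alone. The values were read with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

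The design, the tests, 26 gene lists and the alternatives were fixed before the data were examined, except where a test is said to have been added. Each list was tested per day with limma's camera at a preset correlation of 0.01 between genes (two-sided, adjusted over all 78 tests), and again with an estimated correlation and with fry. Camera compares the genes of a list with all other genes. A list's value is the mean log2 ratio of its measured members, and members were counted over all genes tested and adjusted over the list alone. Of the genes past the threshold with 1 sign on all 4 arrays of a day, the 12 largest increases and the 12 largest decreases are named. Where none passed, the 6 genes per direction with the smallest p and 1 sign on all 4 arrays are named as values that did not pass. For the average, the 8 largest per direction with 1 sign in all 6 replicates are named; for each difference between days, the 5 largest per direction; and from each list, up to 4 members with the smallest p. Placeholder symbols are left out.

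The gene test was checked on simulated data with the spread of the real genes. Of 100 genes per day moved by 0.5 on the log2 scale, 92 to 98% were recovered, and all of 100 moved by 1. False calls were 15 of 207, 16 of 213 and 14 of 212 on the 3 days. On each day this was a larger share than the threshold on adjusted p aims at. The genes that passed in the real data may therefore hold more false calls than that threshold implies. In the simulated list test the 1 raised list was found and 0 of the 77 other tests were called with camera. The simulated genes were drawn independently of each other, with the fitted spread of each gene taken as its true spread. Correlation between genes, on which the list results depend, is therefore not covered by this check. Recovery in the real data may also be lower.

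The alternatives were: all 12 arrays with the replicate as a random block, without and with a dye term; each dye orientation alone; centring, scaling and quantile normalization; a replicate block; a robust prior; each day alone; removal of spots whose dye-swapped arrays differ by over 1; a minimum of 1.5-fold; each replicate left out; and the most variable spot of a gene. For lists, ranks, single spots and lists without shared members were also run. A fit of days 1 and 3 only, the comparison of the dye parts, list tests of the differences between days and 3 further lists were added after the data were seen.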

Results

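Slices of rat entorhinal cortex and hippocampus were grown together, and the entorhino-hippocampal pathway, the axon bundle that joins them, was severed after 15 days. RNA of these axotomized cultures was compared with RNA of intact, non-axotomized cultures 1, 3 and 7 days later. Each day had 2 biological replicates, and each replicate was hybridized to 2 arrays with exchanged dyes, 12 arrays in all. The question, per the series' design text, was which genes alter their transcription at each time after axotomy. Values are log2 ratios of axotomized over non-axotomized cultures, the likely direction from the array titles and channel order. All signs turn if the table runs the other way. Errors are SDs of the 2 replicates of a day (n = 2), and this number of replicates limits the precision.

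The dye-swapped arrays of a replicate were only loosely related gene by gene. Across the 14871 genes, which are not independent, Pearson's r between the 2 arrays of a replicate ran from -0.08 to 0.47, and the share of genes with 1 sign on both ran from 39.7 to 55.9%. After averaging each pair, r between the 2 replicates of a day was 0.48 at day 1, 0.40 at day 3 and 0.29 at day 7.

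At day 1 after axotomy, genes of the dividing cell were higher and genes of stress signalling, cholesterol synthesis and chemokines were lower, as lists in camera's test with its preset correlation. With an estimated correlation none of these lists passed. Over all genes 7 of 23 cell cycle, 3 of 16 stress, 6 of 14 cholesterol and 3 of 26 cytokine and chemokine genes did. Tcf19, a cell cycle factor, rose by 1.08 ± 0.23 (adjusted p = 0.0246), Hmgb2, a chromatin protein, by 0.92 ± 0.033 (adjusted p = 0.0143) and Cdk1, the kinase that starts mitosis, by 0.91 ± 0.23 (adjusted p = 0.0316). The chemokine gene Cxcl1 fell by 1.83 ± 0.14 (adjusted p = 0.0316), which is 3.57-fold on the linear scale. Ddit3 and Atf4, transcription factors of the integrated stress response, fell by 1.28 ± 0.12 (adjusted p = 0.0143) and by 1.04 ± 0.040 (adjusted p = 0.0202).

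In limma's test 88 genes passed at day 1, 55 higher and 33 lower. Further large increases were in Melk, Ckap2, Cenpu, Chaf1b, Cdca3 and Nuf2, which act in mitosis or chromatin assembly and rose by 0.64 to 0.78. Hbb-b1, a globin gene, rose by 1.06 ± 0.39, Cryab, a small heat shock protein gene, by 0.94 ± 0.12 and Hpgds, a prostaglandin D synthase gene, by 0.82 ± 0.16. Among decreases, the stress cytokine gene Gdf15 had -0.99 ± 0.027, Gadd45g -0.84 ± 0.11, the chemokine gene Ccl7 -0.82 ± 0.22, the inflammatory caspase gene Casp4 -0.80 ± 0.071 and the protease inhibitor gene Tfpi2 -0.76 ± 0.11. Ifi27l2b had -0.84 ± 0.039, with its 2 spots at -1.66 and -0.03. Msmo1, Idi1 and Fdps, enzymes of cholesterol synthesis, had -0.83 ± 0.12, -0.78 ± 0.014 and -0.74 ± 0.15. In the test of single spots, 2 spots passed, both lower.

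Of the 26 lists, 2 were higher and 5 lower at day 1, and none of the list results of any day passed with an estimated correlation. With fry, the lists of the cell cycle, of cytokines and chemokines and of cholesterol synthesis passed at day 1 (adjusted p = 0.0136, 0.0311 and 0.041). The 23 cell cycle genes had a mean of 0.31 ± 0.067 (adjusted p = 5.64e-15, and adjusted p = 0.294 with an estimated correlation). Over all genes 7 of them rose, among them Top2a, Plk1 and Mki67, and 16 rose adjusted over the list alone. The microglia and macrophage markers had 0.15 ± 0.064 (adjusted p = 0.00308, 0.0977 without day 1 replicate 2 and 0.0903 with axotomized RNA in Cy5 only; adjusted p = 0.363 with an estimated correlation). None of these 22 genes passed over all genes, and 3 were higher and 1 lower adjusted over the list alone.

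All 14 cholesterol synthesis genes lay below 0 at day 1, with a mean of -0.45 ± 0.11 (adjusted p = 2.99e-18, and adjusted p = 0.339 with an estimated correlation). Over all genes 6 fell, including Sqle, Insig1 and Mvd, and 12 adjusted over the list alone. The 16 cell death and stress genes had a mean of -0.46 ± 0.070 (adjusted p = 4.94e-06, and adjusted p = 0.339 with an estimated correlation). Their median was -0.19, with 5 above 0, so a few large falls carry the mean. Those that fell over all genes were Ddit3, Atf4 and Casp4, and adjusted over the list alone 8 fell and 1 rose. Cytokines and chemokines had -0.25 ± 0.019 over 26 genes (adjusted p = 5.26e-07, and adjusted p = 0.294 with an estimated correlation). Cxcl1, Ccl7 and the adhesion molecule gene Icam1 fell over all genes and 8 adjusted over the list alone. Immediate early genes, which respond to neuronal activity, had -0.27 ± 0.076 (adjusted p = 1.13e-08, and adjusted p = 0.363 with an estimated correlation), and 4 of 17 fell adjusted over the list alone but 0 over all genes. Glycolysis and hypoxia genes had -0.22 ± 0.022 (adjusted p = 4.12e-05, and adjusted p = 0.294 with an estimated correlation), with -0.068 (adjusted p = 0.172) on the arrays with axotomized RNA in Cy3 and -0.37 on those with it in Cy5, and 7 of 15 fell adjusted over the list alone but 0 over all genes.

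The count of 88 genes at day 1 rests on all replicates: it was 8 without day 1 replicate 1, 3 without day 1 replicate 2, 0 without either replicate of day 3 and 36 without either replicate of day 7. These counts are of all genes that passed in a fit. Almost none of the 88 passed without a replicate of day 1 or day 3. In other fits the count ran from 13, with each day alone, over 53, with a replicate block, to 720. The last treated the 12 arrays as separate values in a random block. Of the 88, 9 passed with each day alone, 42 with a replicate block and 88 in the random block.

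**Figure D1:**
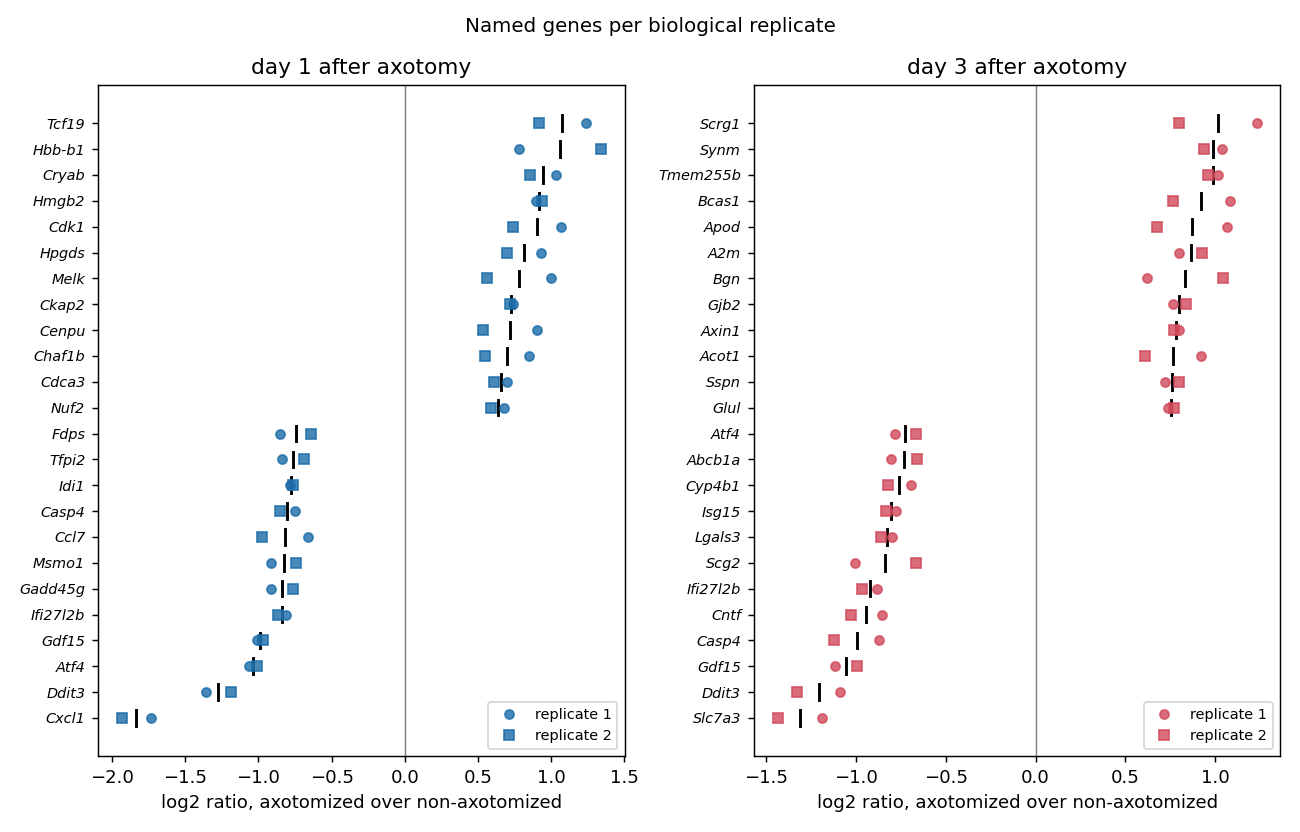
Log2 ratios (x axis) of the named genes at day 1 and day 3, with circles and squares for replicates 1 and 2 and a bar at their mean. At day 1 the means run from -1.83 for Cxcl1 to 1.08 for Tcf19, and at day 3 from -1.31 for Slc7a3 to 1.01 for Scrg1.

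At day 3 after axotomy, genes of astrocytes and of the oligodendrocyte lineage were higher, and the stress genes that were low at day 1 were still low, as lists in camera's test with its preset correlation. With an estimated correlation none of these lists passed. Over all genes 3 of 12 astrocyte, 1 of 16 oligodendrocyte, 2 of 5 precursor and 3 of 16 stress genes did, and the list of reactive astrocytes, at -0.042, did not pass. Glul, the glutamine synthetase gene of astrocytes, rose by 0.75 ± 0.023 (adjusted p = 0.0136), with its 3 spots between 0.01 and 1.19. Synm, an intermediate filament gene, rose by 0.99 ± 0.072 (adjusted p = 0.0185) and Bcas1, a gene of oligodendrocytes, by 0.92 ± 0.22 (adjusted p = 0.0361). Ddit3 fell by 1.21 ± 0.17 (adjusted p = 0.0185), Gdf15 by 1.05 ± 0.089 (adjusted p = 0.0208) and Slc7a3, an amino acid transporter gene, by 1.31 ± 0.18 (adjusted p = 0.0361).

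In limma's test 153 genes passed at day 3, 88 higher and 65 lower. Scrg1 rose by 1.01 ± 0.30, Tmem255b by 0.99 ± 0.041, the lipocalin gene Apod by 0.87 ± 0.28, the protease inhibitor gene A2m by 0.86 ± 0.090, the proteoglycan gene Bgn by 0.83 ± 0.30 and the connexin gene Gjb2 by 0.80 ± 0.048. Axin1, Acot1 and Sspn rose by 0.78 ± 0.020, 0.76 ± 0.22 and 0.76 ± 0.056. Casp4 had -0.99 ± 0.18, Cntf, a neurotrophic factor gene, -0.94 ± 0.12, Scg2, a secretory granule gene, -0.84 ± 0.24 and Lgals3, the galectin-3 gene, -0.83 ± 0.043. The interferon-induced gene Isg15 had -0.81 ± 0.040, Cyp4b1 -0.76 ± 0.090, the efflux pump gene Abcb1a -0.73 ± 0.10 and Atf4 -0.73 ± 0.082. Ifi27l2b had -0.92 ± 0.061, with its spots at -1.95 and 0.10. In the test of single spots 27 were higher and 18 lower.

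Of the 26 lists, 10 were higher and 4 lower at day 3. Those of glycolysis and hypoxia, oligodendrocyte precursors and astrocytes also passed with fry (adjusted p = 0.00939, 0.0311 and 0.0392). The 5 oligodendrocyte precursor genes had 0.38 ± 0.070 (adjusted p = 0.000652, and adjusted p = 0.339 with an estimated correlation). Sox10 and Pdgfra rose over all genes, and 4 of the 5 rose adjusted over the list alone. The 16 oligodendrocyte and myelin genes had 0.28 ± 0.029 (adjusted p = 5.6e-07, and adjusted p = 0.339 with an estimated correlation). Sox10, which both lists hold, rose over all genes and 7 rose adjusted over the list alone. The 12 astrocyte genes had 0.26 ± 0.050 (adjusted p = 6.42e-07, and adjusted p = 0.294 with an estimated correlation). Glul, the connexin gene Gjb6 and the water channel gene Aqp4 rose over all genes, and 8 of the 12 adjusted over the list alone. Microglia and macrophage markers had 0.17 ± 0.070 (adjusted p = 0.000321, and adjusted p = 0.339 with an estimated correlation). Over all genes Lgals3 fell and none rose, and 8 rose and 1 fell adjusted over the list alone.

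The 11 choroid plexus and ependyma genes, markers of tissue next to the hippocampus, had 0.34 ± 0.24 at day 3 (adjusted p = 0.00157, and 0.176 with axotomized RNA in Cy3 only; adjusted p = 0.339 with an estimated correlation), and 0.17 without day 3 replicate 2. None passed over all genes or adjusted over the list alone, and Ttr, the transthyretin gene, had 1.46 ± 1.02. Cell cycle genes had 0.083 ± 0.0091 (adjusted p = 0.0062, 0.222 without day 3 replicate 2 and 0.205 with Cy5 only; adjusted p = 0.339 with an estimated correlation), with 0 of 23 past the threshold over all genes or adjusted over the list alone. Proteoglycan and scar matrix genes had 0.086 ± 0.099 (adjusted p = 0.00542, 0.403 without day 3 replicate 2 and 0.117 with Cy3 only; adjusted p = 0.616 with an estimated correlation), and 0.017 without day 3 replicate 2 and 0.16 without day 3 replicate 1; Bgn rose over all genes and 2 of 21 adjusted over the list alone. Fibroblast and collagen genes had 0.13 ± 0.16 (adjusted p = 0.0282, 0.787 without day 3 replicate 2 and 0.055 with Cy5 only; adjusted p = 0.704 with an estimated correlation), and 0.018 without day 3 replicate 2 and 0.25 without day 3 replicate 1, with 4 higher and 1 lower adjusted over the list alone and 0 over all genes.

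Complement and antigen presentation genes had 0.11 ± 0.018 (adjusted p = 0.0282, 0.175 without day 3 replicate 1 and 0.114 with Cy5 only; adjusted p = 0.735 with an estimated correlation), with 4 of 21 higher adjusted over the list alone and 0 over all genes. Immediate early genes had 0.13 ± 0.062 (adjusted p = 0.037, 0.24 without day 3 replicate 1 and 0.283 with Cy3 only; adjusted p = 0.735 with an estimated correlation), with 2 of 17 higher adjusted over the list alone and 0 over all genes. Cell death and stress genes had a mean of -0.36 ± 0.030 and a median of -0.22, with 6 above 0 (adjusted p = 2.71e-05, and adjusted p = 0.339 with an estimated correlation). Ddit3, Casp4 and Atf4 fell over all genes and 8 of 16 adjusted over the list alone. Interferon response genes had -0.22 ± 0.0045 (adjusted p = 4.92e-08, and adjusted p = 0.339 with an estimated correlation). Ifit2 and Isg15 fell over all genes and 10 of 19 adjusted over the list alone. All 15 glycolysis and hypoxia genes lay below 0, with a mean of -0.21 ± 0.0036 (adjusted p = 5.6e-07, and adjusted p = 0.294 with an estimated correlation), and 4 fell adjusted over the list alone but 0 over all genes. Cholesterol synthesis genes had -0.13 ± 0.0052 (adjusted p = 0.000311, and adjusted p = 0.616 with an estimated correlation), and 6 of 14 fell adjusted over the list alone but 0 over all genes.

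The count of 153 genes at day 3 was 12 without day 3 replicate 1, 6 without day 3 replicate 2, 0 without either replicate of day 1 and 84 without either replicate of day 7. Almost none of the 153 passed without a replicate of day 1 or day 3. In other fits the count ran from 0, with each day alone, to 1064, with the 12 arrays in a random block. A replicate block gave 66 genes, among them 57 of the 153. Quantile normalization gave 75, of which 35 were higher and 40 lower, among them 55 of the 153.

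At day 7 after axotomy no gene passed in limma's test. At an unadjusted p under 0.05 there were 1393 genes, where chance alone gives 743.55, and 3861 single spots, none of which passed. The values with the smallest p, none of which passed (adjusted p = 0.238 for each), included Idi1 of cholesterol synthesis at 0.45 ± 0.084, Nptx2, a gene induced by neuronal activity, at 0.48 ± 0.12 and the myelin gene Mobp at 0.40 ± 0.0048. Tmeff2, Mustn1 and S1pr5 had 0.43 ± 0.087, 0.41 ± 0.055 and 0.31 ± 0.0077. On the other side stood Spp1, the osteopontin gene of activated microglia, at -0.92 ± 0.27, Srgn at -0.44 ± 0.036, Unc119 at -0.36 ± 0.068, the transferrin gene Tf at -0.36 ± 0.12, the lysosomal protease gene Ctsd at -0.33 ± 0.031 and 6330403K07Rikl at -0.28 ± 0.040.

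Of the 26 lists, 3 were higher and 4 lower at day 7, and none passed with fry. All 14 cholesterol synthesis genes lay above 0, with a mean of 0.21 ± 0.077 (adjusted p = 5.36e-09, and adjusted p = 0.363 with an estimated correlation), and 6 rose adjusted over the list alone. Immediate early genes had 0.30 ± 0.25 (adjusted p = 4.63e-07, and adjusted p = 0.426 with an estimated correlation), and 0.12 without day 7 replicate 2 and 0.47 without day 7 replicate 1, with 8 of 17 higher adjusted over the list alone. Oligodendrocyte and myelin genes had 0.19 ± 0.14 (adjusted p = 1.19e-06, and adjusted p = 0.339 with an estimated correlation), and 0.091 without day 7 replicate 1 and 0.30 without day 7 replicate 2, with 4 of 16 higher adjusted over the list alone. Microglia and macrophage markers had -0.20 ± 0.048 (adjusted p = 6.55e-08, and adjusted p = 0.294 with an estimated correlation), with 5 of 22 lower adjusted over the list alone. Choroid plexus and ependyma genes had -0.32 ± 0.034 (adjusted p = 0.00303, 0.0966 without day 7 replicate 2 and 0.168 with Cy5 only; adjusted p = 0.339 with an estimated correlation), with 0 of 11 past the threshold adjusted over the list alone and Ttr at -2.17 ± 0.54. Interferon response genes had -0.11 ± 0.10 (adjusted p = 0.00207, 0.617 without day 7 replicate 2 and 0.055 with Cy5 only; adjusted p = 0.616 with an estimated correlation), and -0.043 without day 7 replicate 2 and -0.18 without day 7 replicate 1, with 1 of 19 lower adjusted over the list alone. Complement and antigen presentation genes had -0.089 ± 0.17 (adjusted p = 0.0273, 0.142 with Cy5 only and 0.0974 with Cy3 only; adjusted p = 0.735 with an estimated correlation), with 1 higher and 4 lower of 21 adjusted over the list alone, and the mean was 0.031 without day 7 replicate 2 and -0.21 without day 7 replicate 1.

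The count of 0 genes at day 7 became 18 without day 7 replicate 2, 15 with quantile normalization, 288 with the 12 arrays in a random block and 194 with a dye term added. The other fits and the other replicates left out gave 0.

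**Figure D2:**
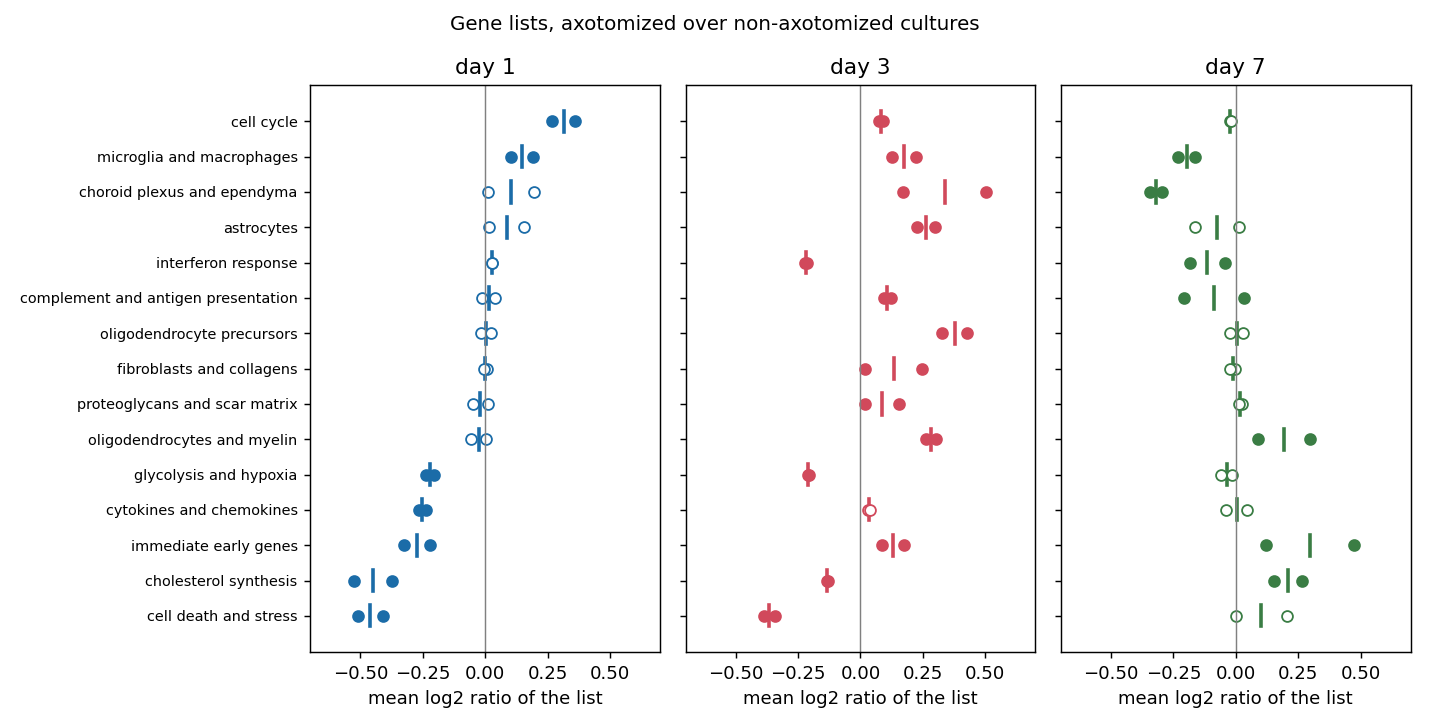
Mean log2 ratio (x axis) of each list that passed the camera test on at least 1 day, with a circle per biological replicate and a bar at their mean. Filled circles mark lists that passed with the preset correlation, as the cholesterol synthesis list did at -0.45 on day 1 and at 0.21 on day 7.

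The lists for neurons, axon growth and vessels did not pass on any day. A mean near 0 does not mean that no member moved, since rises and falls cancel. Adjusted over the list alone, 4 reactive astrocyte genes were higher and 4 lower at day 1. Of the regeneration-associated genes, 3 were higher and 6 lower at day 1. At day 3, 4 neurotrophic factor and receptor genes were higher and 2 lower. Neuron and synapse genes had -0.013 ± 0.11, 0.021 ± 0.074 and 0.039 ± 0.083 at days 1, 3 and 7, interneuron genes 0.0070 ± 0.11, 0.070 ± 0.071 and 0.061 ± 0.056, hippocampal principal cell genes 0.0040 ± 0.071, 0.083 ± 0.042 and 0.00058 ± 0.0021, and cortical principal cell genes 0.0085 ± 0.032, -0.014 ± 0.0040 and 0.027 ± 0.00035. Regeneration-associated genes, which injured neurons that regrow an axon express, had -0.079 ± 0.0047, -0.023 ± 0.040 and 0.0012 ± 0.071; of these Gadd45a fell at day 3 by 0.56 ± 0.15 (adjusted p = 0.0494). Axon guidance genes had -0.011 ± 0.026, 0.030 ± 0.050 and 0.025 ± 0.00088, and in this list the ephrin gene Efnb1 and the ephrin receptor gene Ephb1 rose at day 3 by 0.28 ± 0.075 and 0.36 ± 0.097 (adjusted p = 0.0468 for each). Myelin inhibitors and their receptors had -0.025 ± 0.095, 0.029 ± 0.0046 and 0.065 ± 0.088. Endothelial genes had -0.023 ± 0.031, 0.028 ± 0.036 and 0.0044 ± 0.0021, and extracellular proteases -0.0028 ± 0.034, 0.024 ± 0.0028 and -0.050 ± 0.033. Neurotrophic factors and their receptors had -0.068 ± 0.057, 0.016 ± 0.087 and 0.036 ± 0.025. Reactive astrocyte genes had 0.0059 ± 0.0086, -0.042 ± 0.022 and -0.0023 ± 0.0081, the first with a camera direction below 0, and Lcn2, an acute phase gene of this list, fell at day 1 by 0.68 ± 0.15 (adjusted p = 0.0281). The chemokine gene Cxcl12 rose at day 3 by 0.60 ± 0.035 (adjusted p = 0.0232) in a cytokine list whose mean was then 0.035 ± 0.0051.

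On average over the 3 days, 47 genes passed in limma's test, 25 higher and 22 lower, and those named have 1 sign in all 6 replicates. Nuf2, a kinetochore gene, had an average of 0.28 (adjusted p = 0.04), Kif20a, a mitotic kinesin gene, 0.23 and Timeless, a replication fork gene, 0.24, while Ccdc34, Arhgef19, Lsm11, Lxn and Siglec5 had 0.38, 0.36, 0.29, 0.26 and 0.26. Lcn2 had -0.38 (adjusted p = 0.0468), the transcription factor gene Bhlhe40 -0.32, Cyp4b1 -0.30, the mitochondrial enzyme gene Pck2 -0.25, Tf -0.25, the endoplasmic reticulum chaperone gene Dnajb9 -0.23, Amn -0.21 and Ifit2 -0.17. Some averages came from unequal days, as for Nuf2, which had 0.64 ± 0.063 at day 1 and 0.084 ± 0.0062 at day 7. The count of 47 was 1 without either replicate of day 1, 1 and 0 without day 3 replicates 1 and 2, 3 without day 7 replicate 1 and 34 without day 7 replicate 2. A replicate block gave 0, a minimum of 1.5-fold left 4, 2 of the 32 ways to turn the signs of the replicates gave 47 or more, the real signs included, and arrays with the axotomized RNA in Cy5 only gave 2761.

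The comparison between days asked which genes respond differently with time. From day 3 to day 7, Ddit3 rose by 1.44 (adjusted p = 0.0412), Scg2 by 1.40, Casp4 by 1.11, Atf4 by 1.09 and Asns, the asparagine synthetase gene that ATF4 controls, by 0.97. Spp1 fell, with a difference of -1.47 (adjusted p = 0.0447), as did Tmem255b with -1.30, Synm with -1.11, A2m with -1.10 and Plekhb1 with -0.995. From day 1 to day 7, Ddit3 rose by 1.51 (adjusted p = 0.0409), Atf4 by 1.40, and the cholesterol synthesis genes Idi1, Msmo1 and Sqle by 1.23 (adjusted p = 0.0141), 1.17 and 0.94. Hmgb2 fell, with a difference of -0.9997 (adjusted p = 0.0427), as did Ckap2 with -0.76, the fructose transporter gene Slc2a5 with -0.70, Nat8f5 with -0.63 and Ctsd with -0.62.

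In limma's test 53 genes differed between days 3 and 7, 25 with a higher ratio at day 7 and 28 with a lower one. Between days 1 and 7 there were 18, 9 in each direction. Between days 1 and 3 none passed, with 1316 genes at an unadjusted p under 0.05 where chance gives 743.55. The F test over all days gave 20 genes. Without day 1 replicate 1, day 1 replicate 2, day 3 replicate 1, day 3 replicate 2, day 7 replicate 1 and day 7 replicate 2, in this order, the count for days 3 and 7 was 0, 0, 3, 0, 1 and 19, for days 1 and 7 it was 1, 2, 0, 0, 8 and 22, for days 1 and 3 it was 1, 4, 2, 0, 4 and 4, and in the F test it was 1, 1, 1, 0, 1 and 24, and each difference named above no longer passed in 4 to 6 of these 6 settings. For days 3 and 7 and days 1 and 7, most genes that passed in these fits were not among the 53 or the 18. A replicate block gave 0, 11 and 0 genes for days 3 and 7, days 1 and 7 and days 1 and 3. It gave 0 in the F test, and 5 of the 18 were among the 11. The most variable spot of a gene gave 1, 2, 0 and 0. The 12 arrays in a random block gave 917, 868 and 389 genes for these pairs of days. They gave 1292 genes with any difference between days (F test). Quantile normalization gave 66, 92 and 91 for the pairs.

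**Figure D3:**
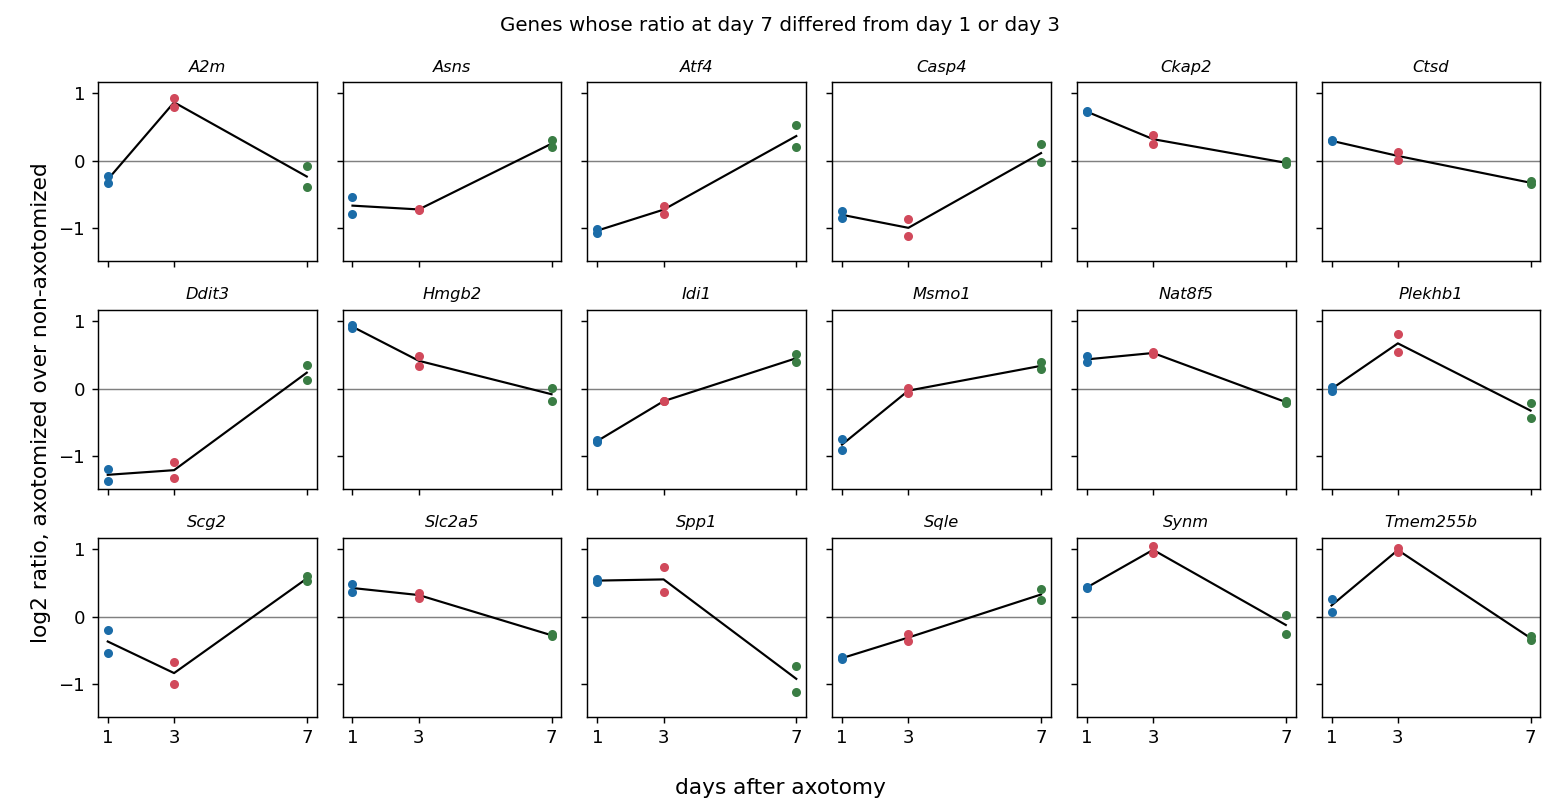
Log2 ratio (y axis) against days after axotomy (x axis) for 18 genes whose ratio at day 7 differed from that of day 1 or day 3, with a dot per biological replicate and a line through the means. Ddit3 runs from -1.28 at day 1 to 0.24 at day 7 and Hmgb2 from 0.92 to -0.08.

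Days 1 and 3 shared 18 genes with the same direction and 1 with the opposite direction. Among genes that rose, Arhgef19, Ccdc34, Ckap2, Cyp4f1, Nat8f5 and Slc2a5 passed at both days. Among genes that fell, 12 were shared. These were Atf4, Atf5, Ddit3, Asns, Mthfd2, Slc38a2, Slc7a1 and Eif2s2, which act in amino acid or one-carbon metabolism, translation or the stress response, and Casp4, Fermt2, Gdf15 and Ifi27l2b. With independent genes, 0.33 shared rises and 0.14 shared falls would be expected (Fisher's exact test, p = 8.3e-07 and 5.48e-21). Both days share 1 estimate of the spread per gene and genes are not independent. These p therefore overstate the case, and how many would be shared by chance stays unknown. Igf2bp2, an RNA-binding protein gene and the 1 with the opposite direction, fell by 0.43 at day 1 and rose by 0.35 at day 3, a difference that did not pass (adjusted p = 0.0655). Of the 55 genes that rose at day 1, 54 had the same sign at day 3 and 24 at day 7. Of the 33 that fell, 26 and 6 did. Of the 88 genes that rose at day 3, 60 had the same sign at day 1 and 31 at day 7, and of the 65 that fell, 57 and 25 did.

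Across all genes, Pearson's r (Spearman's rho) between mean ratios was 0.30 (0.28) for days 1 and 3, -0.20 (-0.13) for days 1 and 7 and -0.11 (-0.03) for days 3 and 7; genes are not independent replicates. Between single replicates of different days, r reached 0.073 for days 1 and 7 and 0.084 for days 3 and 7, so these 2 negative values turned sign in at least 1 pair. The lowest of the 4 pairs for days 1 and 3 had 0.056.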

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

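The tests on the share of glial cells, on dye bias, on the direction of the table and on the spread and size at day 7, and the list tests between days, were chosen only after the results were seen.

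The genes named and lists called at days 1, 3 and 7 were searched for single arrays far from the other 3 of their day (Dixon's test, 4 arrays per group). The median and the SD of the arrays of each day were searched too. Of 94 groups, 9 held such an array, where chance gives about 1 in 20 for independent values. The 4 arrays are 2 replicates in 2 dye orientations and the groups share arrays, so the 9 cannot be set against chance. At day 1 they were Casp4, with -0.97 on an array of replicate 2 against -0.76 to -0.73 on the others, and the microglia and macrophage list, with 0.27 against 0.09 to 0.12. At day 3 they were A2m, with 1.07 against 0.79 to 0.80, Slc7a3, with -0.95 against -1.47 to -1.40, Ddit3, with -0.83 against -1.37 to -1.28, Cntf, with -1.22 against -0.88 to -0.83, Abcb1a, with -0.51 against -0.82 to -0.79, and the astrocyte list, with 0.38 against 0.22 to 0.24. At day 7 it was Unc119, with -0.20 against -0.43 to -0.41.

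The response differed between days in limma's test of the difference itself for 53 genes between days 3 and 7, 18 genes between days 1 and 7 and 20 genes in the F test over all days. With a replicate block, a pairing that is not excluded, the counts were 0, 11 and 0. Only 5 of the 18 genes for days 1 and 7 were among these 11. Each difference named here no longer passed in 4 to 6 of the 6 fits without 1 replicate. Among the genes that passed, the largest rises from day 3 to day 7 were Ddit3 (1.44), Scg2 (1.40), Casp4 (1.11), Atf4 (1.09) and Asns (0.97), and the largest falls Spp1 (-1.47), Tmem255b (-1.30), Synm (-1.11), A2m (-1.10) and Plekhb1 (-0.995). From day 1 to day 7 they were Ddit3 (1.51), Atf4 (1.40), Idi1 (1.23), Msmo1 (1.17) and Sqle (0.94), and Hmgb2 (-0.9997), Ckap2 (-0.76), Slc2a5 (-0.70), Nat8f5 (-0.63) and Ctsd (-0.62).

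Lists also differed between days, by camera with the preset correlation adjusted over 78 tests. With an estimated correlation none of these differences passed (adjusted p = 0.255 to 0.654). From day 1 to day 3 the mean rose for immediate early genes (0.40), oligodendrocyte precursors (0.37), cholesterol synthesis (0.32), oligodendrocytes and myelin (0.31), cytokines and chemokines (0.29), choroid plexus and ependyma (0.23), astrocytes (0.18), fibroblasts and collagens (0.13), proteoglycans and scar matrix (0.10), neurotrophic factors and receptors (0.085) and axon guidance (0.041), and fell for the interferon response (-0.25) and the cell cycle (-0.23). From day 3 to day 7 it rose for cell death and stress (0.47), cholesterol synthesis (0.34), glycolysis and hypoxia (0.17), immediate early genes (0.17) and the interferon response (0.10), and fell for choroid plexus and ependyma (-0.66), oligodendrocyte precursors (-0.37), microglia and macrophages (-0.37), astrocytes (-0.34), complement and antigen presentation (-0.20), the cell cycle (-0.10) and proteoglycans and scar matrix (-0.068). From day 1 to day 7 it rose for cholesterol synthesis (0.66), immediate early genes (0.57), cell death and stress (0.56), cytokines and chemokines (0.25), oligodendrocytes and myelin (0.22) and glycolysis and hypoxia (0.18), and fell for choroid plexus and ependyma (-0.42), microglia and macrophages (-0.35) and the cell cycle (-0.34).

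Outside the genes, 731 spots with no listed gene turned with the dyes on the arrays.

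Atf4 and Ddit3 were low at days 1 and 3 and not at day 7. If ATF4 acts less in axotomized cultures, its other targets are low too, and 23 measured targets that had not been looked at had a mean of -0.23 at day 1 and -0.34 at day 3, as this explanation needs. The 17 endoplasmic reticulum chaperones and related genes had -0.28 at day 1 (adjusted p = 2.32e-11, and 0.0814 with an estimated correlation). A wider fall of endoplasmic reticulum stress may thus be part of it, and the values needed by both explanations are there. This list was not wholly separate from earlier results. Hspa5, at -0.93 on day 1, is also in the cell death and stress list, and Dnajb9 was named for its low average. A table that runs the other way cannot be told apart from these, since the 731 spots that turn with the dyes speak for columns that share 1 direction but do not tell which. Why the cultures would differ in this response was not tested.

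Cholesterol synthesis genes were low at day 1 and high at day 7 as a list, which did not pass with an estimated correlation on either day (adjusted p = 0.339 and 0.363), and none of the 14 passed over all genes at day 7. Fatty acid synthesis genes had -0.17 ± 0.042 at day 1, with 12 of 15 below 0, and 0.057 ± 0.054 at day 7. At day 1 the adjusted camera p was 5.02e-06 over the 9 tests of added lists, and 0.0587 with an estimated correlation. Both means were less than 0.5 times as far from 0 as the cholesterol list. With the SD of the list added, this held narrowly at day 1 and not at day 7. The spread of the cholesterol list itself, -0.45 ± 0.11 at day 1, was not counted and is wider than this margin. Neither day therefore decides whether a change of lipid synthesis as a whole is the cause. Fewer astrocytes and oligodendrocytes at day 1 is argued against by their lists, at 0.086 and -0.026. At day 7 the oligodendrocyte list was high too (0.19, against 0.21 for cholesterol synthesis), but the astrocyte list was not (-0.074 ± 0.13). A higher share of oligodendrocytes thus stays open for that day. At day 3 the astrocyte and oligodendrocyte lists were high (0.26 ± 0.050 and 0.28 ± 0.029) while cholesterol synthesis was low (-0.13 ± 0.0052). This argues against the share of these cells as the cause over all 3 days, though none of these lists passed with an estimated correlation. Dye bias is argued against by the arrays of day 1, the highest of which had a list mean of -0.23. A response of cholesterol synthesis itself to axotomy, a hypothesis here, stays open, as does the direction of the table.

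No gene passed at day 7. The spread between the replicates of day 7 was not wider, with a ratio of 0.999 to that of days 1 and 3. The 3 days share 1 estimate of the spread, so a wider one would have acted on all days. This ratio therefore could not decide why calls were missing at day 7 alone. Smaller changes at day 7 may account for the lack of calls: the SD over genes of the mean ratio was 0.101, against 0.117 at day 1 and 0.121 at day 3. Why the changes were smaller was not tested.

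For the 47 genes that passed on average over the days, the signs of the 6 replicates were turned in all 32 ways. Of these, 2 gave as many genes, the real one included, so chance is not excluded. The highest of the others gave 278 genes and turned both replicates of day 7, which points to a structure of the samples: day 7 against days 1 and 3.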

How the results depend on the processing

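The fit of days 1 and 3 only was added after the data were seen. The 96 values of named genes gave 1836 comparisons, of which 1145 stayed on their side of the threshold, 664 no longer passed and 27 passed in addition. Their direction says nothing about stability, since most were chosen for 1 sign on all arrays or replicates and several settings leave the mean as it is. Without a replicate of day 1 or day 3, 82 to 84 of the 84 values that had passed no longer did, and the lone replicate left was assumed to vary like the other days. Of the 28 list results, 28 kept their call with centring and with a replicate block, 27 with single spots, 24 with ranks, 23 of 27 without shared members, 21 with Cy5 only, 23 with Cy3 only, 6 with fry and 0 with an estimated correlation. No dim spots could be filtered, since the table gives no signal over background. Except where named, the cause was not tested.

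Counts of genes are given in the order day 1, day 3, day 7, average, days 1 and 3, days 3 and 7, days 1 and 7, genes with any difference between days (F test), where they moved by over 1.5 times. With the 12 arrays in a random block, which has more residual degrees of freedom by construction and took the 2 arrays of a replicate as negatively correlated (-0.17, and 0.23 with a dye term), they were 720, 1064, 288, 851, 389, 917, 868 and 1292, and with a dye term added 594, 958, 194, 695, 290, 832, 726 and 1124. With the axotomized RNA in Cy5 only they were 654 at day 1, 298 at day 3, 2761 on average and 2, 4 and 64 between days; in Cy3 only they were 56 at day 1, 2645 on average, 16 and 2 for days 3 and 7 and days 1 and 7, and 0 in the F test. Averages over 1 dye keep the dye's own effect by construction. Quantile normalization gave 75 at day 3, 15 at day 7, 114 on average, 91 for days 1 and 3, 92 for days 1 and 7 and 133 in the F test. Replicate numbers were weakly related for days 1 and 3 and not for the pairs with day 7 (r of deviations 0.26, -0.07 and 0.01), so a pairing is not excluded, and the replicate block gave 53, 66, 0 on average, 0 for days 3 and 7, 11 for days 1 and 7 and 0 in the F test. The robust prior gave 17 on average, 11 for days 1 and 7 and 1 in the F test. Each day alone gave 13 and 0 at days 1 and 3, with fewer samples behind the spread. Without spots with a dye-swap gap over 1 there were 121 on average, 14 for days 1 and 3, 48 for days 1 and 7 and 55 in the F test. A minimum of 1.5-fold left 33, 40 and 4 on average by construction. The most variable spot gave 32 at day 1, 5 on average, 1 and 2 for days 3 and 7 and days 1 and 7, and 0 in the F test. Days 1 and 3 only gave 36 and 84.

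Single spots at days 1, 3 and 7 were 1297, 2304 and 678 in the random block, 996, 2005 and 402 with a dye term, 1822, 1545 and 804 in Cy5 only, 1405, 1224 and 1142 in Cy3 only and 155, 133 and 17 with quantile normalization. The replicate block and each day alone gave 0 and 0 at days 1 and 3, the robust prior 9 at day 3, centring 4 at day 1, centring and scaling 28 at day 3, and removal of dye-swap gaps 31 and 320.

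Leaving out 1 replicate gave 0 to 36 genes at day 1, 0 to 84 at day 3, 0 to 18 at day 7, 0 to 34 on average, 0 to 4 for days 1 and 3, 0 to 19 for days 3 and 7, 0 to 22 for days 1 and 7 and 0 to 24 in the F test. Single spots ran from 0 to 15, 0 to 140 and 0 to 28. These fits have fewer samples behind the spread, and the genes that passed in them were often not those of the main fit. Lists past the threshold ran from 7 to 8, 11 to 14 and 7 to 8, not always the same lists: of the 28 list results 25 to 28 were kept, and without day 7 replicate 2 the calls of choroid plexus, interferon and complement at day 7 were lost.

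Of the lists past the threshold at days 1, 3 and 7, an estimated correlation gave 0, 0 and 0, fry 3, 3 and 0, and Cy5 only 4 at day 7. Ranks ended the calls of complement at days 3 and 7 and of immediate early genes and fibroblasts at day 3, as did lists without shared members, and single spots that of fibroblasts at day 3. The complement and antigen presentation list at day 7 ran from -0.21 without day 7 replicate 1 to 0.031, a turned sign, without day 7 replicate 2 (adjusted p = 0.597). Genes past the threshold on any day had r of 0.47 for days 1 and 3 and -0.36 for days 1 and 7. Single pairs of replicates had 0.056 at the lowest for days 1 and 3, and turned sign at the highest, 0.073, for days 1 and 7 and 0.084 for days 3 and 7.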

Other observations

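The 3 lists in this part were chosen only after the data were seen, and their p are adjusted over their 9 tests.

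Beyond Atf4 and Ddit3 themselves, further targets of ATF4 were low as a list after axotomy. Of 23 measured ATF4 targets, 21 lay below 0 at day 1 and 23 at day 3, with means of -0.23 and -0.34. Over all genes none passed at day 1 and 5 fell at day 3, and the serine synthesis genes Phgdh and Psat1 had 0.13 and -0.03 at day 1. The adjusted camera p was 2.97e-14 and 3.58e-21, and with an estimated correlation adjusted p was 0.0342 on both days. Before adjustment, camera with an estimated correlation gave p = 0.00759 at day 1 and p = 0.004 at day 3. The adjustment covered only the added lists, a smaller family of tests than that of the lists fixed beforehand. This pass therefore cannot be compared with the fixed lists, none of which passed with an estimated correlation. At day 3 Shmt2 and Psph, enzymes of serine and glycine metabolism, fell by 0.62 and 0.51, Lonp1, a mitochondrial protease gene, by 0.53, the asparaginyl-tRNA synthetase gene Nars1 by 0.49 and Stc2 by 0.30. At day 7 the mean of the list was 0.058.

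Chaperones of the endoplasmic reticulum and related genes were low as well: all 17 lay below 0 at day 1 and at day 3, with means of -0.28 ± 0.13 and -0.37 ± 0.067. The adjusted camera p was 2.32e-11 and 1.7e-16, but with an estimated correlation neither passed (0.0814 and 0.0587). At day 3 Dnajc3, Dnajb9 and Herpud1 fell by 0.66, 0.41 and 0.33 over all genes. At day 7 the mean was 0.12, with 13 of 17 above 0. This opposite direction passed with an adjusted camera p of 0.00823, but not with an estimated correlation (0.303). Fatty acid synthesis genes had -0.17 at day 1 (adjusted camera p = 5.02e-06, and 0.0587 with an estimated correlation) and -0.058 at day 3, where Srebf1, a transcription factor gene of lipid synthesis, fell by 0.49.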
